A study of Mus musculus with 6 samples.

How the data were processed

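Poly(A)-selected RNA from mouse ovarian surface epithelial cells was sequenced 7 days after the cells received an adenovirus carrying GFP alone (Ad-GFP, 3 libraries) or Cre recombinase with GFP (Ad-Cre-GFP, 3 libraries), per the labels. Cre was used to delete Lats1 and Lats2. Total RNA was taken with a column kit and mRNA was enriched on poly(A) beads, per the labels' protocols. The deposited values are whole-number read counts per gene, 1 column per library, from BAM files of aligned reads, per the file headers. The submitters' processing notes name kallisto 0.46.2, sleuth 0.30.1 and the build GRCm38. The aligner, the counting tool, its treatment of strand and of reads that match several places, and the annotation release are not given in the sources used here. Counts of genes with near-identical copies, and of overlapping or antisense genes, are therefore uncertain.

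The table held 48440 genes, of which 21434 had a count of 0 in all 6 libraries. Symbols and coordinates were taken from GENCODE mouse release 21 (GRCm38) by gene ID without its version, and 48058 IDs matched. The 382 IDs without a match held 0.0381% of all counts. Where several IDs share a symbol, the symbol was kept for the ID with most counts. Library totals ran from 18690235 to 30304033 counts, and the 3 Ad-Cre-GFP libraries were all deeper than the 3 Ad-GFP libraries. A count of 0 in a library allows up to 3 counts, which was 0.0990 to 0.161 CPM (counts scaled to a library total of 1e+06). Such limits and the 95% exact binomial intervals given for low counts cover counting error only.

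Replicate pairs of each group were compared by a chi-square over genes with at least 20 counts in the pair. The chi-square per gene was 2.04 to 4.27, against 1 for sampling noise alone, so no pair agreed within sampling noise and all 6 libraries were kept. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

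Genes were filtered with filterByExpr on the group, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, no replicate block) in R 4.3.3, leaving 14811 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are Ad-Cre-GFP over Ad-GFP. Their standard errors (SE) are the log2 fold change divided by the square root of the quasi-likelihood F. CPM values are TMM-scaled and given as mean ± SD of 3 libraries; sums over lists use CPM without TMM scaling. Unless another tool or a left-out library is named, adjusted p-values of single genes are from this edgeR test on all 6 libraries. Before the data were examined, 34 gene lists of pathways, cell type markers and RNA quality were fixed. The 28 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation, which also lowers its degrees of freedom from 14809 to 4, and fry were run beside it. Lats2 was left out of the YAP/TAZ list.

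Genes are named by rules also fixed before the data were examined. They are Lats1, Lats2 and Cd274; the 10 largest called rises and 10 largest called falls with a mean of at least 5 CPM and no overlap between the groups, unnamed gene models left out; up to 3 called members with the smallest adjusted p of each list; and a fixed set of Hippo, AKT, keratin, p53 and proliferation genes. Some genes that these rules name are not reported here. Further list members are named as examples, chosen after their values were seen.

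Alternatives were other size factors, upper-quartile scaling, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the quasi-likelihood test without robust dispersion, leaving out mitochondrial genes, a replicate block and leaving out each library. Thinning all libraries to the smallest total, removing trends with GC content and transcript length, and exchanging the degrees of freedom of both camera settings, were added after seeing the data. Near-identical copies of transcripts were searched for with minimap2 2.31 in the GENCODE transcripts, as alignments of at least 200 bases at 90% identity.

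The edgeR test was tested on simulated data with the means and library sizes of the 14811 genes and 200 changed genes. In a first simulation with per-gene dispersions, 28 of 189 calls were false (14.8%), above the upper limit of 10% set for the check. The check was then widened to 10 simulations for each of 2 dispersion models, and only the model with dispersions on the fitted trend kept a limit. With trend dispersions, false calls averaged 4.53% (2.89% to 6.29%), and 91.2% of log2 changes of 1 and 76.9% of log2 changes of 0.5 were recovered. With per-gene dispersions, false calls averaged 8.27% (4.85% to 15.8%), above the nominal 5%. The corresponding averages with per-gene dispersions were 8.40% for limma-voom and 4.18% for DESeq2. These simulations changed 200 genes, far fewer than were called in the data, so their rates do not carry over to the real calls. A list shifted by 0.5 was called by camera in 10 of 10 simulations with either correlation setting, and no other list was called; these simulations draw each gene independently, so they do not test correlated lists.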

Results

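The transcriptome of mouse ovarian surface epithelial cells, the single layer of cells that covers the ovary, was compared with and without deletion of Lats1 and Lats2. LATS1 and LATS2 are the kinases of the Hippo pathway that phosphorylate and restrain the coactivators YAP and TAZ. There were 3 control libraries (Ad-GFP) and 3 knockout libraries (Ad-Cre-GFP). The control libraries held 21546287, 25363462 and 18690235 counts and the knockout libraries 29642448, 30304033 and 27734527. The series title names AKT activity and PD-L1 expression, and genes of both were followed here.

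The targeted genes were read first. Lats1 (chromosome 10, 7681214 to 7716460, GRCm38) fell from 159 ± 8.74 CPM to 37.1 ± 1.36 CPM (SD, n = 3), a log2 fold change of -2.10 ± 0.04 (SE, adjusted p = 5.79e-20). Lats2 (chromosome 14, 57689662 to 57758388) fell less, from 130 ± 2.16 to 98.7 ± 1.97 CPM (-0.39 ± 0.03, adjusted p = 3.82e-10). Knockout levels were 23.3% of control for Lats1 and 76.2% for Lats2. Every knockout library lay below every control library for both genes. The counts cover whole genes, and the exons removed by Cre are not given in the sources used here, so the level of Lats2 does not measure its deletion.

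Of 14811 genes tested, 10344 (69.8%) were called, 5040 higher and 5304 lower in the knockout. Which direction had more calls depended on the scaling, so the near-even split is not a result in itself. A change of at least 2-fold was called for 2045 genes, 926 higher and 1119 lower. Most called changes were small, with a median absolute log2 change of 0.49. The groups did not overlap for 73.0% of tested genes, against 10% by chance. The first principal component held 89.5% of the variance and separated the groups. Replicates were tight, with a common biological coefficient of variation of 3.06%, so that small changes passed the test. Ad-GFP replicate 3, the library with the fewest counts, stood apart from the other controls on the second principal component (3.15% of the variance), at -18.69 against 8.85 and 11.1. Without it 10124 genes were called. Deletion, Cre exposure and any difference between the cultures coincide in this design and cannot be separated.

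**Figure D1:**
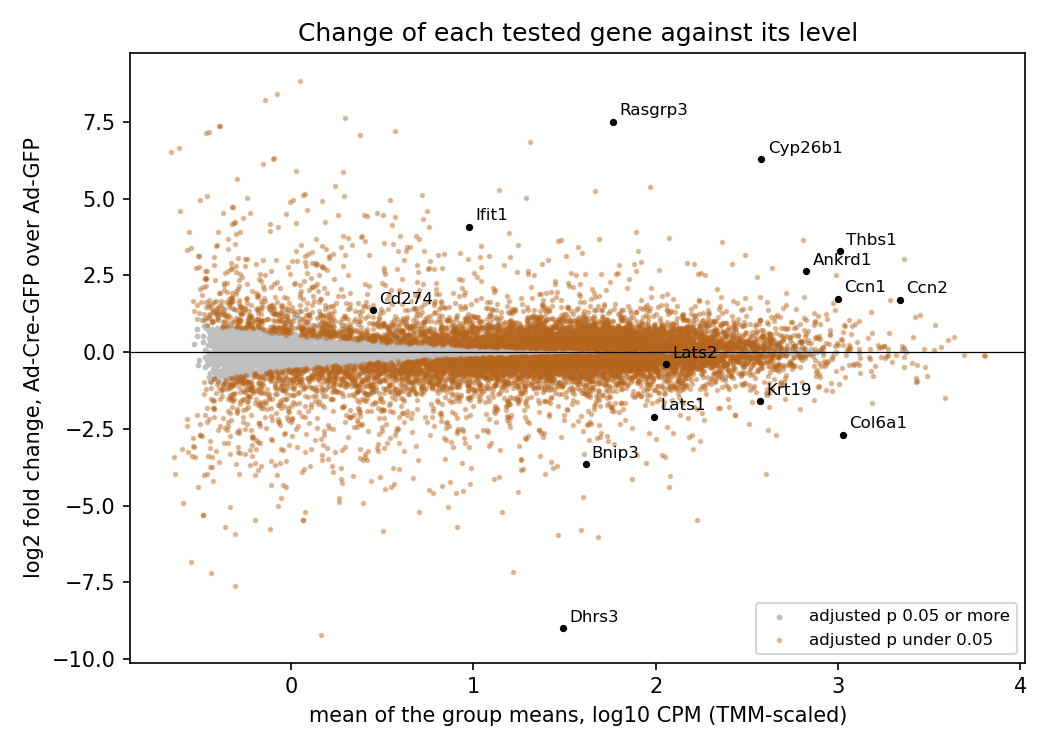
Log2 fold change of each tested gene (vertical axis) against the log10 of its mean CPM (horizontal axis), with genes called at adjusted p under 0.05 in brown and the others in grey. Of the 14811 genes, 10344 were called; Cyp26b1 rose and Dhrs3 fell among the largest changes, while Lats2 lies close to 0 at -0.39.

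Target genes of YAP and TAZ rose. Of 21 members, 14 rose, 5 fell and 2 were not called (14 and 6 adjusted over the list alone), with a median log2 change of 0.84 (camera adjusted p = 3.45e-13; adjusted p = 0.1003 with an estimated correlation). Ankrd1, a muscle ankyrin repeat protein, rose from 186 ± 15.8 to 1151 ± 27.1 CPM (2.63 ± 0.05). The matricellular genes Ccn1 and Ccn2 rose by 1.74 ± 0.04 and 1.71 ± 0.03, Amotl2, which encodes an angiomotin that binds YAP, by 1.32 ± 0.03, and Ddah1 by 2.88 ± 0.04. The largest fall was that of Nt5e, the ectoenzyme CD73, at -2.33. Yap1 (0.01 ± 0.03, adjusted p = 0.736) and Wwtr1, which encodes TAZ (-0.04 ± 0.03, adjusted p = 0.295), were not called. Of 25 tested Hippo pathway components, 15 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.000494; adjusted p = 0.302 with an estimated correlation). The median log2 change of this list was only 0.16. Tead4, a DNA-binding partner of YAP, rose by 1.96 ± 0.06, Wwc2 by 0.99 ± 0.03 and Vgll3 by 0.85 ± 0.03, and the largest fall was that of Amotl1 (-0.99 ± 0.04). Of 14 contractile and SRF-regulated genes, 13 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 4.02e-06, and 0.302 with an estimated correlation). Ad-GFP replicate 3 was the lowest control library for 10 of these 14 genes. Without it 13 still rose and 1 fell, with a median of 0.90. Tpm1 rose by 0.90 ± 0.03, Actn1 by 0.92 ± 0.03 and Cnn2 by 0.99 ± 0.04.

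**Figure D2:**
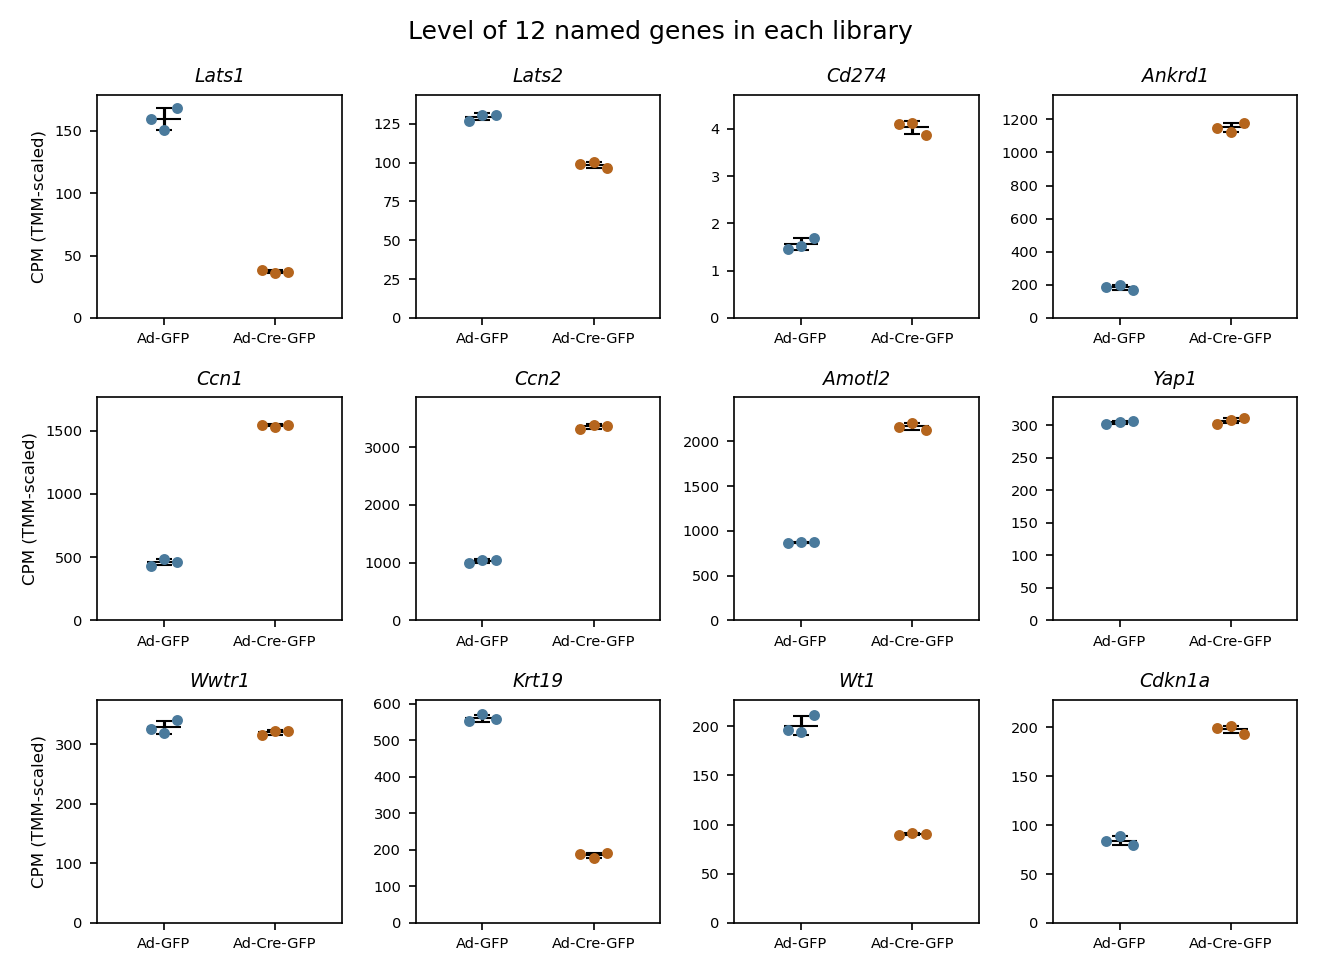
CPM (vertical axes, from 0) of 12 genes in the 3 Ad-GFP and 3 Ad-Cre-GFP libraries; points are libraries, and the horizontal mark and bars are the mean and SD. Ankrd1 rose from 186 to 1151 CPM and Lats1 fell from 159 to 37.1 CPM, while Yap1 and Wwtr1 were not called.

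Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), rose 2.59-fold from a low level, 1.56 ± 0.12 to 4.03 ± 0.14 CPM (log2 change 1.37 ± 0.15, adjusted p = 4.08e-08). The other PD-1 ligand gene, Pdcd1lg2, had 0 counts in the controls and 2 in the knockout, too few to test. Immune checkpoint ligands went both ways. Of 11 tested, 5 rose and 5 fell, also when adjusted over the list alone. Camera gave no call (adjusted p = 0.696) and a downward sign, whereas the median (0.09) and mean (0.25) were above 0. Vsir rose from 3.14 ± 0.278 to 10.1 ± 0.347 CPM, Lgals9 from 36.9 ± 1.15 to 105 ± 4.92 CPM, and Cd47, a signal that restrains phagocytosis, fell from 441 ± 21.8 to 106 ± 4.08 CPM (-2.06 ± 0.04).

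Transcripts of the AKT pathway went both ways. Akt1 rose by 0.37 ± 0.03 (adjusted p = 5.50e-10), while Akt2 fell (-0.34 ± 0.03, adjusted p = 1.47e-08). Of 29 PI3K-AKT-mTOR components, 10 rose, 13 fell and 6 were not called, with the same counts adjusted over the list alone. There was no list call (camera adjusted p = 0.696), but camera looks for a shift in 1 direction, and rises and falls offset each other in it. Pik3cb rose by 1.06 ± 0.03 and Irs2 by 0.64 ± 0.03, and Pik3r2 fell (-0.78 ± 0.03). The largest change in this list was the fall of Inpp4b, from 6.30 to 0.275 CPM (-4.47 ± 0.27). AKT activity itself is not measured by transcript counts. Among 23 growth factors and receptor tyrosine kinases, 13 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.00675; adjusted p = 0.302 with an estimated correlation). Nrg1, a ligand of ERBB receptors, rose by 2.89 ± 0.04 and Pdgfb by 1.37 ± 0.03, and Pdgfc fell (-1.44 ± 0.04).

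Interferon-stimulated genes rose. Of 31 tested, 29 rose, none fell, and Irf1 and Stat2 were not called, also adjusted over the list alone. The median log2 change was 2.51 (camera adjusted p = 1.24e-10; adjusted p = 0.302 with an estimated correlation). Ifit1 rose from 1.05 ± 0.15 to 17.8 ± 2.58 CPM (4.09 ± 0.15), Ifit2 by 2.51 ± 0.06 and Ifit3 by 4.33 ± 0.17. Genes of MHC class I antigen presentation had 8 rises and 5 falls among 15, also adjusted over the list alone, with no list call (camera adjusted p = 0.696). H2-D1 rose by 0.83 ± 0.04, H2-K1 by 0.54 ± 0.04, and H2-T23 fell (-1.05 ± 0.05); such class I genes are close paralogs, and their counts are uncertain. Of 13 cytokines and chemokines, 7 rose and 5 fell, also adjusted over the list alone, with no list call (camera adjusted p = 0.121). Cxcl12 rose from 95.2 ± 1.78 to 1195 ± 4.02 CPM, Csf1 from 290 ± 6.67 to 1660 ± 12.4 CPM, and Cxcl1 fell from 51.2 ± 3.64 to 11.1 ± 0.361 CPM.

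Cell cycle genes rose together with p53 target genes. All 21 genes of DNA replication and the G1/S step rose, by a median of 1.02 (camera adjusted p = 1.04e-12; adjusted p = 0.302 with an estimated correlation), as did all 26 mitotic genes, by a median of 0.58 (camera adjusted p = 3.22e-06; adjusted p = 0.541 with an estimated correlation). Both counts held adjusted over the list alone. Ad-GFP replicate 3 was the lowest control library for all 21 and all 26 of these genes. Without it all 21 and all 26 still rose, by medians of 0.98 and 0.52. Ccnd1 (cyclin D1) rose by 1.38 ± 0.03, Rrm1 by 1.20 ± 0.04, Kif23 by 0.94 ± 0.04, Ccna2 by 0.73 ± 0.04, Birc5 by 0.67 ± 0.04 and Mki67 by 0.30 ± 0.05. Of 23 p53 targets, 16 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.000535; adjusted p = 0.302 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.23 ± 0.04, Plk2 by 1.15 ± 0.03 and Mdm2 by 0.93 ± 0.03, and Ddit4 fell (-2.89 ± 0.04). The 12 apoptosis regulators had 5 rises and 5 falls, also adjusted over the list alone, with no list call (camera adjusted p = 0.952). Bid rose by 1.75 ± 0.06, Bcl2l1 rose by 0.54 ± 0.03 and Bmf fell (-4.58 ± 0.17). In this list the camera sign was upward and the median (-0.06) and mean (-0.20) were below 0.

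Genes of glycolysis and the hypoxia response fell. Of 20, 19 fell and Gapdh was not called (20 fell adjusted over the list alone), with a median log2 change of -1.10 (camera adjusted p = 5.90e-22; adjusted p = 0.227 with an estimated correlation). Bnip3, a mitophagy receptor, fell from 76.4 ± 0.933 to 6.04 ± 0.369 CPM (-3.66 ± 0.06), Pdk1, a kinase that holds back pyruvate dehydrogenase, by -2.65 ± 0.04, and Pfkl, a phosphofructokinase, by -2.06 ± 0.03. Gapdh, Bnip3 and 6 other members have near-identical annotated copies, and their counts are uncertain. Cholesterol synthesis and uptake genes fell in 19 of 20, also adjusted over the list alone, by a median of -0.70 (camera adjusted p = 5.23e-08; adjusted p = 0.302 with an estimated correlation). Hmgcs1 fell from 406 ± 4.73 to 203 ± 7.28 CPM, and Cyp51 (-0.88 ± 0.03) and the regulator Srebf2 (-0.83 ± 0.03) fell too.

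**Figure D3:**
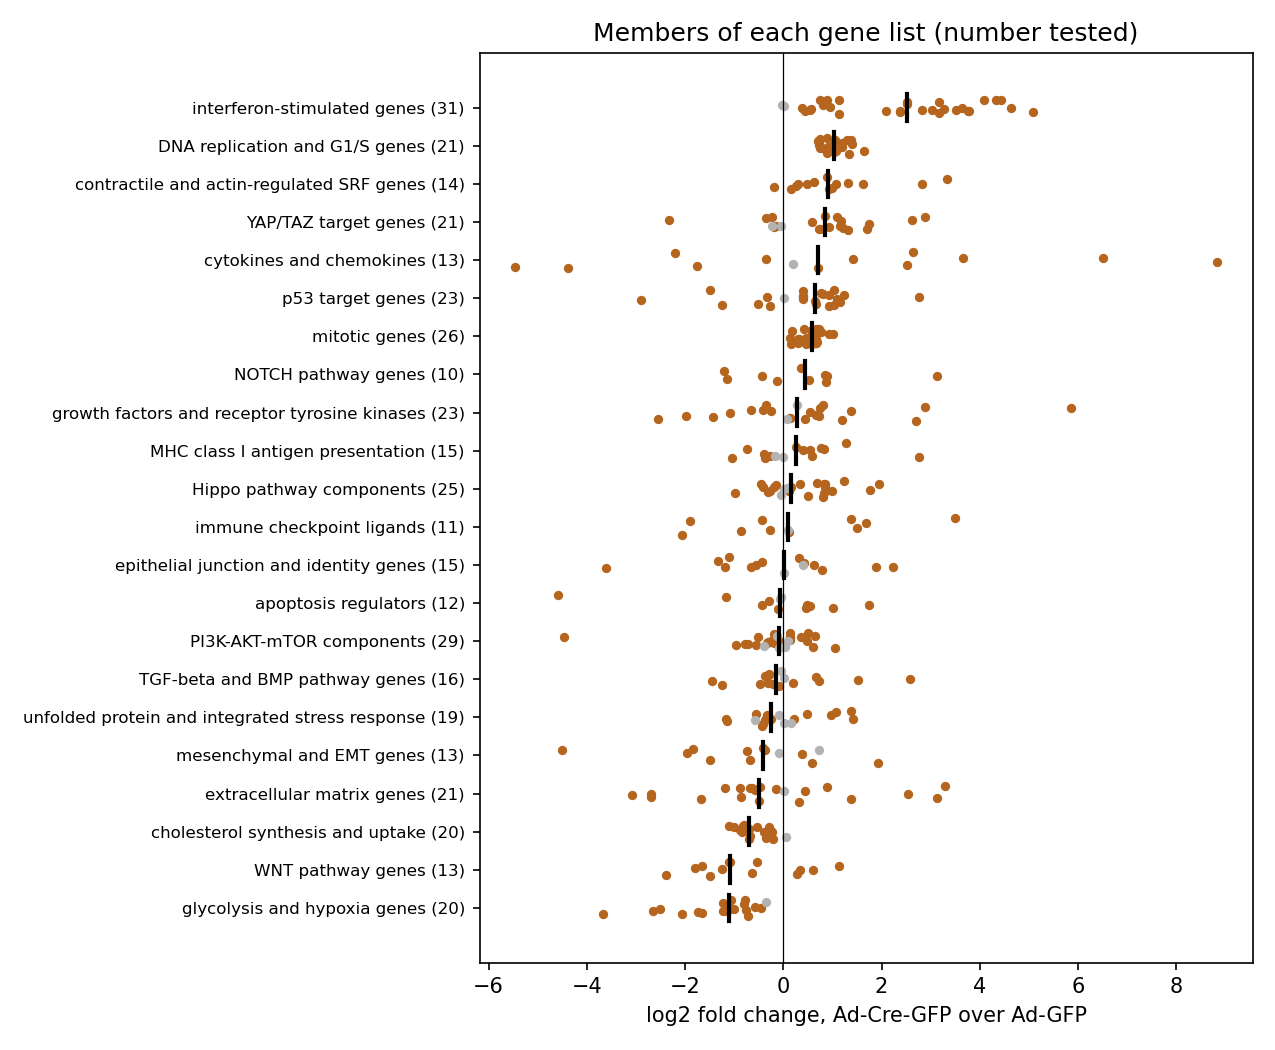
Log2 fold change (horizontal axis) of each tested member of the pathway lists with at least 5 tested members, with called members in brown, others in grey and the list median as a black bar. The median is highest for interferon-stimulated genes, 2.51, and lowest for glycolysis and hypoxia genes, -1.10.

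Epithelial, matrix and signalling genes changed in both directions. Among 19 tested markers of ovarian surface epithelium and mesothelium, 6 rose and 11 fell, also adjusted over the list alone, with no list call (camera adjusted p = 0.140). Krt19 (-1.60 ± 0.03), Gata4 (-1.37 ± 0.03), Wt1 (-1.15 ± 0.04) and Krt8 (-0.19 ± 0.03) fell, and Msln (1.10 ± 0.03) and Krt18 (0.08 ± 0.03) rose; the call of Krt18 was lost without Ad-GFP replicate 1 (adjusted p = 0.0658) and without Ad-Cre-GFP replicate 1 (adjusted p = 0.0578). Of 15 epithelial junction genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.696, downward, with a mean of -0.15 and a median of 0.02). F11r (-1.34 ± 0.03), Jup (-0.66 ± 0.03) and Cdh1, E-cadherin (-0.44 ± 0.03), fell. Of 13 mesenchymal genes, 3 rose and 8 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0916). Cdh2, N-cadherin, rose by 1.93 ± 0.03, and Fn1 (-1.49 ± 0.03) and Prrx1 (-1.95 ± 0.05) fell. Of 21 extracellular matrix genes, 7 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.541 with an estimated correlation). This call was lost without Ad-Cre-GFP replicate 2 (adjusted p = 0.0800), without Ad-Cre-GFP replicate 3 (adjusted p = 0.0788) and when GC and length trends were removed (adjusted p = 0.169). Thbs1 rose from 189 ± 11.8 to 1848 ± 49.5 CPM, and the collagen VI genes Col6a1 (-2.69 ± 0.04) and Col6a2 (-2.70 ± 0.04) fell.

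Of 13 WNT pathway genes, 4 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.0275; adjusted p = 0.302 with an estimated correlation). The call was lost without Ad-GFP replicate 2 (adjusted p = 0.0508) and when GC and length trends were removed (adjusted p = 0.0555). Wnt5a (-1.66 ± 0.04) fell, Fzd7 fell from 29.0 ± 0.893 to 10.3 ± 0.467 CPM, and Axin2 rose by 1.13 ± 0.08. Of 16 TGF-beta and BMP pathway genes, 5 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.773, upward, with a mean of 0.06 and a median of -0.15). Tgfb3 (-1.25 ± 0.03) and Tgfbr1 (-1.46 ± 0.04) fell. Of 10 NOTCH pathway genes, 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.696), with rises of Hey2 (3.12 ± 0.10) and Jag1 (0.89 ± 0.04) and a fall of Jag2 (-1.21 ± 0.05). The unfolded protein and integrated stress list had 6 rises and 9 falls among 19, also adjusted over the list alone (camera adjusted p = 0.265, downward, with a median of -0.25 and a mean of 0.00061). Xbp1 (-1.15 ± 0.03), Dnajb9 (-1.16 ± 0.05) and Pdia4 (-0.56 ± 0.03) fell, while Psat1 (1.43 ± 0.13) and Phgdh (1.38 ± 0.11), enzymes of serine synthesis, rose.

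The 10 largest called rises by the rule on level were those of Rasgrp3, Pappa2, Cyp26b1, Npr3, S100a7a, Aif1l, Ntf3, Fras1, Ifit3 and Scn3a, with log2 changes from 7.50 for Rasgrp3 to 4.33 for Ifit3. Rasgrp3, an activator of RAS proteins, rose from 0.607 ± 0.327 to 116 ± 2.82 CPM. Cyp26b1, which degrades retinoic acid, rose from 9.38 ± 3.21 to 750 ± 20.7 CPM. The protease gene Pappa2 rose from 0.333 ± 0.151 to 40.7 ± 0.483 CPM. The 10 largest falls included those of Dhrs3, Dmbt1, Gda, Hmcn1, Il13ra1, Il33, Medag, Enpp1 and Cp, with log2 changes from -8.995 for Dhrs3 to -4.71 for Cp. Dhrs3, a retinaldehyde reductase, fell from 1301 to 1431 counts per control library to 1 to 6 counts per knockout library, 529-fold lower (95% exact binomial interval 287 to 1103). Il33, a cytokine of the interleukin-1 family, fell from 328 ± 37.6 to 7.39 ± 0.409 CPM.

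Among markers of other cell types, the called endothelial and pericyte markers rose, the called stromal fibroblast, theca, immune and oviduct markers fell, and granulosa markers went both ways. Summed over the list, immune cell markers were 12.97 ± 1.25 CPM in control and 7.33 ± 0.256 CPM in knockout libraries; of 2 tested, Cd14 fell (-1.23 ± 0.11) and Cd68 was not called. Endothelial markers were 10.6 ± 0.848 and 24.0 ± 0.757 CPM; of 4 tested, Flt1 (1.62 ± 0.11), Ptprb (1.01 ± 0.09) and Kdr rose, Kdr from 4 to 173 counts in all, and Pecam1, Cdh5 and Tie1 had at most 8 counts in any library. Pericyte and smooth muscle markers were 8.41 ± 0.247 and 24.8 ± 1.54 CPM, mostly Mcam, which rose by 1.66 ± 0.07; the call of Notch3 (0.87 ± 0.32) was lost with DESeq2 (adjusted p = 0.0996) and without each of 3 libraries in turn, Ad-GFP replicates 1 and 2 (adjusted p = 0.0734 and 0.114) and Ad-Cre-GFP replicate 1 (adjusted p = 0.0845). Theca and steroidogenic markers were 132 ± 0.319 and 95.2 ± 1.17 CPM; both tested members fell, Star (-2.11 ± 0.09) and Nr5a1 (-0.22 ± 0.03). Granulosa markers were 141 ± 6.32 and 326 ± 6.37 CPM, mostly Inhbb (137 and 322 CPM without TMM scaling). Of 5 tested, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.236). Inhbb changed by 1.27 ± 0.03, Amh by 1.17 ± 0.21 and Inha by -1.52 ± 0.20. Stromal fibroblast markers were 409 ± 7.77 and 300.3 ± 10.3 CPM; of 5 tested, 4 fell, also adjusted over the list alone (camera adjusted p = 0.0509), among them Dcn (-1.91 ± 0.05), Pdgfra (-1.98 ± 0.40) and Dpt, which had 29 counts in all control and 2 in all knockout libraries (18.9-fold lower, 95% exact binomial interval 4.78 to 164). Oviduct markers were 4.98 ± 0.585 and 3.63 ± 0.211 CPM, with 1 fall (Epcam, -3.60 ± 0.39) among 3 tested, and oocyte markers were 0.360 ± 0.0640 and 0.476 ± 0.159 CPM with none tested.

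Quality lists gave no list call. Mitochondrially encoded mRNAs had 6 rises and 2 falls among 13 (camera adjusted p = 0.696), with mt-Co1 at -0.13 ± 0.04, mt-Co3 at -0.17 ± 0.04 and mt-Cytb at 0.15 ± 0.04. Ad-GFP replicate 3 was the highest control library for 12 of these 13 genes. Ribosomal protein genes had 14 rises and 2 falls among 34 (camera adjusted p = 0.429), with Rpl27 at 0.81 ± 0.06, Rpl3 at 0.34 ± 0.06 and Rpl8 at 0.23 ± 0.03; many have near-identical pseudogenes. Immediate-early and heat-shock genes had 6 rises and 7 falls among 15 (camera adjusted p = 0.696, upward, with a median of -0.06 and a mean of -0.05), with Dusp1 at 2.64 ± 0.04, Egr1 at -2.01 ± 0.12 and Jun at -0.60 ± 0.05. These 3 counts were the same adjusted over the list alone. Of the 28 lists tested, camera called 12 with the preset correlation and 0 with an estimated correlation, whose lowest adjusted p was 0.1003; 4 lists had an unadjusted p under 0.05 with an estimated correlation, and fry called 21.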

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

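Thinning to equal depth, removing GC and length trends and exchanging camera's degrees of freedom were chosen after seeing the data; the other alternatives were not. Genes called numbered 9351 to 10854 over all alternatives and 9932 to 10124 leaving out a library. The counts called, higher, lower and changed at least 2-fold stayed within 1.5 times their values. The direction with more calls changed with the scaling. TMM gave 5040 higher and 5304 lower, size factors of the DESeq2 type 5186 and 5162, and upper-quartile scaling 4920 and 5437. Scaling places the median log2 change near 0 (-0.0065 with TMM), so the sign of very small changes depends on it. Lats1, Lats2 and Cd274 kept direction and call in all 17 alternatives. Leaving out a library gave -2.14 to -2.06 for Lats1, -0.41 to -0.36 for Lats2 and 1.33 to 1.43 for Cd274. Outside these ranges, Cd274 was 1.26 at equal depth and Lats2 was -0.33 with GC and length trends removed. Same-numbered libraries correlated by 0.14, 0.11 and 0.09 in their deviations from group means, above the highest value for unlike numbers (0.061). Each library correlated best with its own number, so a pairing by number is possible, though the labels do not state one. In both groups replicate 2 had the most counts and replicate 3 the fewest, so a pairing cannot be told apart from an effect of depth. Deviations from a group mean also sum to 0, so these matches are not independent of each other. The fit without a block had been set as the main one beforehand, and a replicate block called 10478 genes. Of 2269 values of 134 other named genes, 6 lost the call (Notch3 4, Krt18 2) and none reversed.

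With an estimated inter-gene correlation no list stayed called: the adjusted p was 0.1003 for YAP/TAZ targets, 0.227 for glycolysis and hypoxia, 0.541 for mitotic and extracellular matrix genes, and 0.302 for Hippo components, growth factors and receptors, interferon-stimulated, G1/S, p53, contractile, WNT and cholesterol genes. The estimate also lowers camera's degrees of freedom from 14809 to 4, and neither change alone ended all 12 calls. With the estimated correlation and 14809 degrees of freedom 5 lists stayed called, and the adjusted p was 0.110 for growth factors and receptors and for G1/S, 0.117 for interferon-stimulated, 0.416 for mitotic and extracellular matrix, 0.0648 for contractile and 0.121 for cholesterol genes. With the preset correlation and 4 degrees of freedom 7 stayed called, and it was 0.0616 for Hippo and p53, 0.108 for growth factors and receptors, 0.162 for extracellular matrix and 0.161 for WNT genes. Leaving out 1 library gave 0.00379 to 0.0800 for extracellular matrix, 0.0120 to 0.0508 for WNT, 0.0464 to 0.102 for mesenchymal and 0.0371 to 0.0790 for stromal fibroblast lists. Removing GC and length trends gave 0.169 for extracellular matrix and 0.0555 for WNT genes. Without a low-count filter the mesenchymal (0.0492) and stromal fibroblast (0.0245) lists were called, the latter also without mitochondrial genes (0.0493). The cause of these changes with a left-out library, trends or filter was not tested. Fry, which does not compare a list with other genes, called checkpoint ligands (0.00927, downward), cytokines (0.000949), surface epithelium (7.22e-05), junction (0.0104), mesenchymal (0.000157), NOTCH (0.00861), unfolded protein (0.0131), granulosa (0.000660) and stromal fibroblast (7.22e-05) lists. Depth limits Cd274, at 32 to 123 counts per library, and simulations with per-gene dispersions gave 8.27% false calls at a nominal 5%.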

Other observations

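The tests of leukocyte transcripts, of Cre exposure, of library labels and of Lats2 exons were chosen after the result was seen. The genes in the next paragraph were also chosen after their values were seen.

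No list of complement genes was tested, and the following are single genes. C3, the central complement component, fell from 20.7 to 3.42 CPM (-2.59 ± 0.10, SE), Lbp, which binds bacterial lipopolysaccharide, from 33.7 to 1.41 CPM (-4.56 ± 0.18), and C1s1 and C1ra, proteases of the classical pathway, by -0.81 ± 0.04 and -0.94 ± 0.04. Cd59a, a membrane inhibitor of complement, was not called (-0.19 ± 0.27, adjusted p = 0.547 by edgeR). Igf2 had 4 counts in all control and 326 in all knockout libraries (62.5-fold higher, 95% exact binomial interval 24.2 to 231). Vegfa rose by 1.20 ± 0.04.

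Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real split, which is the real split itself: it called 10344 genes and the highest other split 0. For gene lists under camera with the preset correlation, the real split called 12 lists and the highest other split 8, again with 1 split as large. With 10 splits the share cannot fall under 0.1. Every other split puts libraries of both groups on each side. The group difference then enters the spread within each side, so the 0 called genes there are no evidence against a random grouping. Part of that difference also stays between the sides, so the 6 to 8 lists called there are not a baseline. These splits therefore decide neither question.

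The rise of interferon-stimulated genes was set against 3 explanations. Leukocytes would bring their abundant transcripts, but Ptprc, Tyrobp, Fcer1g, Lyz2 and Laptm5 together stayed at or under 0.371 CPM in each knockout library, below the highest control library (0.418 CPM). After thinning all libraries to the same size, 29 of 31 members were still called higher, so the calls did not need the greater depth of the knockout libraries. CPM already divides by depth and thinning keeps the expected ratios, so thinning could hardly have changed the direction. Exposure to Cre cannot be told apart from loss of Lats1 and Lats2, since 0 control libraries received Cre. Ifnb1 had 3 counts in all knockout and 0 in all control libraries, too few to say whether the cells transcribed interferon.

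The fall of glycolysis and hypoxia genes was not explained by reads shared with near-identical copies, since the 12 members without an annotated copy had a median log2 change of -1.18. A hypothesis is that the hypoxia response as a whole was lower in the knockout cultures. It was tested on 15 other hypoxia-inducible genes picked before their values were seen: 14 were called lower, 0 higher, and the median was -0.95 (camera p = 8.32e-13 with the preset correlation, 0.0108 with an estimated correlation), which is consistent with it. Vegfa, itself hypoxia-inducible, was left out because its rise had been seen, and goes the other way. Whether cell density or oxygen differed between the cultures, or deletion lowered the response, stays open, as nothing in the labels separates them.

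Lats2 counts fell to 76.2% of control, against 23.3% for Lats1. Mislabelled libraries were argued against by Lats1 itself, whose highest knockout CPM was 0.256 times its lowest control CPM. Reads from Lats2 exons outside the deleted part may hold up its count; this cannot be told apart from incomplete deletion or from a change in its transcription, since counts per exon were not used here.

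A further hypothesis is a lower retinoic acid signal in the knockout cultures. Dhrs3, Rarb (-2.74 ± 0.31) and Stra6 (-2.14 ± 0.43), which retinoic acid induces, fell, and Cyp26b1, which degrades it, rose; Aldh1a1, which makes it, also rose (0.48 ± 0.03), and Cyp26b1 is itself induced by retinoic acid in many cells, which goes against a lower signal. Of 12 other induced genes picked before their values were seen, 8 could be tested: 5 were called lower, Hoxa5 was higher and 2 were not called. Their median was -0.42 (camera p = 0.0120 with the preset correlation), which met the bound set beforehand, but p was 0.179 with an estimated correlation. The hypothesis therefore has weak backing here.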
